A study of Mus musculus with 6 samples.

How the data were processed

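Each of the 6 libraries held islets of 1 male mouse at postnatal day 24, 3 of them labelled control and 3 labelled Dpy30 knockout, with 100 to 200 islets picked by hand per mouse, per the labels' protocols. Messenger RNA was enriched by its poly(A) tail from 1000 ng of total RNA, and strand-specific libraries were made with 9 cycles of amplification, per the labels' protocols. The submitters' processing notes name Trimmomatic, Salmon and DESeq2 and the builds GRCm38 and mm10. Their versions, the transcript annotation and the settings are not given in the sources used here.

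For each library the authors deposited a Salmon transcript table with estimated counts, TPM (levels scaled by length and library total) and transcript lengths, per the file headers. Estimated counts need not be whole, because a read that fits several transcripts is shared among them. The authors deposited signal values per gene and library too, which from their values are gene counts scaled between libraries and were not used here; how they were scaled is not given in the sources used here. The authors also deposited a table of their own comparison with log2 fold changes and p-values per gene, per the file headers; it was used for comparison with the fits made here.

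Transcripts were assigned to genes by transcript identifier, without its version, in GENCODE release vM21 on GRCm38; 139852 of 140948 transcripts were matched, and they held 99.6 to 99.7% of estimated reads in each library, above the required 95%. Unmatched transcripts stayed out. Estimated counts were summed per gene and rounded to whole numbers. Where several genes share a symbol, the symbol stayed with the gene of most reads. Genes were kept by edgeR's filterByExpr (minimum count 10), which left 16430. Libraries were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, group being the only term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, two-sided. CPM are on TMM-scaled library sizes, with a prior count of 2 where taken to log2 for comparing libraries. The SE of a log2 fold change was taken from the size of the change and its F statistic. The common biological coefficient of variation was 0.26.

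A set of 30 gene lists was fixed before the data were examined. It covers H3K4 methyltransferase complexes, H3K4 demethylases, hormones, beta cell maturity, stimulus-secretion coupling, granules, islet transcription factors, alpha, delta, immature, normally silent, acinar, ductal, endothelial, mesenchymal, immune, Schwann and red blood cell genes, cell cycle, unfolded protein response, p53 targets, immediate early genes, interferon response, glycolysis, tricarboxylic acid cycle, cholesterol synthesis, OXPHOS, ribosomal proteins, mitochondrial mRNAs and Hox genes. Lists were tested with camera (limma 3.58.1, voom values, preset correlation 0.01) and adjusted over the 30 lists; 16 passed. None of them passed with an estimated correlation, where the lowest adjusted p was 0.17. Of the 16, 7 passed fry, which asks whether a list's genes move one way on balance without comparing them with other genes: hormones, beta cell maturity, stimulus-secretion coupling, islet transcription factors, delta cell genes, glycolysis and the tricarboxylic acid cycle.

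Named genes followed a rule fixed before the data were examined: Dpy30 and the hormones; the 8 higher and 8 lower genes of largest change among called genes of at least 5 CPM whose groups did not overlap and whose symbol is not a predicted or clone-based name; up to 4 members of each list with the smallest p; and 14 genes of beta cell identity, immaturity or proliferation. Gm42418, Lars2, Fosb and the imprinted and neuronal genes other than Nnat were chosen after their values were seen. Some genes that the rule takes are not reported here.

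Replicate numbers are shared between the groups in the labels, so a fit with the number as a block was planned beside the group-only fit. Deviations from the group means correlated at 0.427, 0.135 and 0.196 between control and knockout libraries of the same number, all above 0.1, so by the rule set for this check the numbers were taken to pair the libraries. The 6 pairs of different numbers ran from -0.318 to 0.14, and the highest, control replicate 3 with knockout replicate 2, lay above the 0.135 of the pair numbered 2. The pairing therefore rests on weak evidence. The group-only fit stayed the main one, as planned, and results with the block are given beside it. With the replicate block 2430 genes were called. The labels do not say what a number marks.

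The procedure was tested on simulated counts for this comparison, in 5 sets of about 16186 tested genes with 200 changed genes each, drawn from the real means and library sizes and the gene-wise dispersions fitted to them. The edgeR test recovered 24.8% of genes changed 2-fold and 83% of those changed 4-fold, 0 in the wrong direction. Of its calls 9.1% were unchanged genes, above the nominal 5%. DESeq2 1.42.0 recovered 50.4% of genes changed 2-fold with 22% unchanged genes among its calls, and limma-voom 20.2% with 7.7%. With the replicate block edgeR recovered 15% of genes changed 2-fold and 78.2% of those changed 4-fold, and 10.6% of its calls were unchanged genes, in counts simulated without an effect shared within pairs. In these sets a gene with a 2-fold change was thus more often missed than found by the edgeR test. The sets held 200 changed genes, against 1634 genes called in the data. The adjusted threshold was therefore stricter in the sets, and the share found in the data was not measured.

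Alternatives planned before the data were examined were RLE and upper quartile scaling, library sizes without hormones, DESeq2, limma-voom, no filter, a minimum mean of 1 CPM, a transcript length offset, protein-coding genes alone, an adjusted p below 0.01, an absolute log2 fold change of at least 1, the replicate block and each library left out in turn. An acinar covariate, the split of Dpy30 by exon 4, removal of a length trend, list counts and the correlation with the authors' table without each library, and the length trend with the block were added after the data were seen. Single measures of 3 against 3 libraries were compared by exact permutation, which cannot give a p below 0.1.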

Results

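Polyadenylated RNA was sequenced from pancreatic islets of male C57BL/6 mice at postnatal day 24. The 6 libraries came from 3 control mice and 3 Dpy30 knockout mice, 1 mouse per library. Dpy30 is a core subunit shared by the complexes that methylate histone H3 at lysine 4 (H3K4), and the series asks what that mark does while islet endocrine cells mature after birth. The labels name neither the Cre line nor the deleted part of the gene. The estimated reads per library were 25208847, 25354384 and 24575889 in control replicates 1 to 3, and 22694892, 17131515 and 23976598 in knockout replicates 1 to 3. Reads of the insulin genes Ins1 and Ins2 took 13.6, 21.9 and 16.4% of the control libraries and 6.51, 9.66 and 9.50% of the knockout libraries. Libraries of the same group correlated at a Pearson r of 0.9591 to 0.9749 on log2 CPM (read counts scaled to library size) across genes, and all pairs differed by far more than sampling noise (chi-square per degree of freedom 56.3 to 342.7 within groups). Knockout replicate 2 stood apart in the predicted gene Gm42418, which took 15.8% of its scaled reads and 0.102 to 0.215% in the other libraries.

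The targeted gene differed in which of its transcripts were present. Dpy30 (ENSMUSG00000024067) lies on the minus strand of chromosome 17 from 74299474 to 74323944 in GRCm38, and its exon 4, 143 bp long, spans 74307720 to 74307862. Transcripts that skip this exon held 81.2% ± 0.84 of the Dpy30 reads in knockout islets and 3.15% ± 2.46 in control islets (SD, n = 3 each). The 3 knockout libraries read 82.2% (95% exact binomial interval 79.3 to 84.7, counting error only), 81.0% (78.2 to 83.6) and 80.5% (77.6 to 83.2), from 794, 844 and 815 Dpy30 reads. The control libraries read 5.24% (3.59 to 7.28), 0.439% (0.0882 to 1.24) and 3.78% (2.52 to 5.33), from 614, 702 and 775 reads. The 2 groups did not overlap, and an exact two-sided permutation test of 3 against 3 gave p = 0.1, the smallest value it allows. Transcripts with exon 4 fell from 28.3 ± 3.52 to 7.25 ± 2.46 CPM (log2 fold change -1.98, SE 0.25, adjusted p = 0.00402, edgeR quasi-likelihood test). Transcripts without it rose from 0.893 ± 0.662 to 31.3 ± 10.2 CPM (log2 fold change 5.13, SE 0.60, adjusted p = 0.00301 in the same test). The split by exon 4 was added with the transcript values of both groups in view, the labels name no deleted exon, and Salmon shares out by estimate those reads that fit both kinds of transcript.

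**Figure D1:**
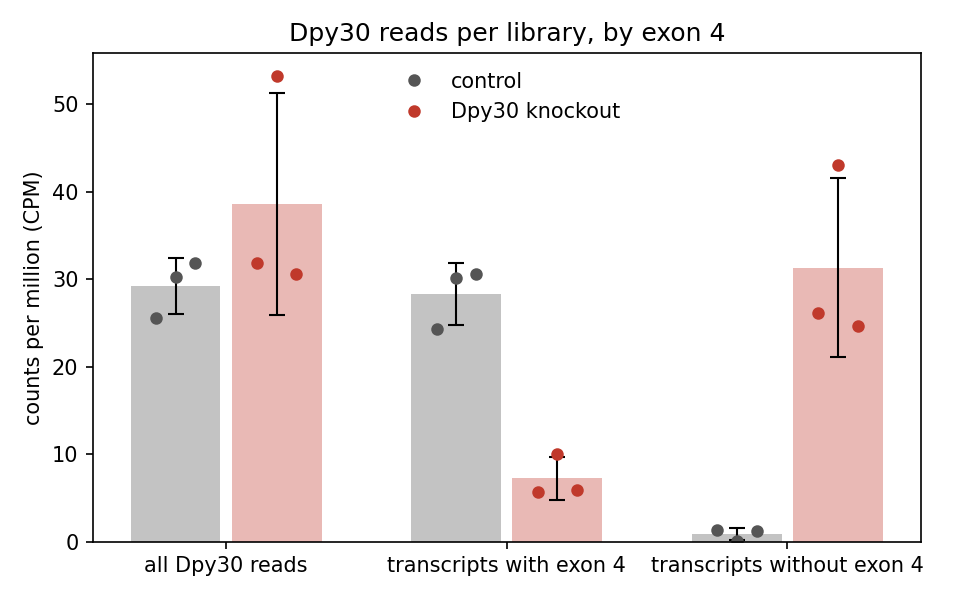
Scaled read counts (CPM) of Dpy30 in each library for all its transcripts, those with exon 4 and those without it. Points are libraries, bars are means of 3 and error bars are SD. Transcripts with exon 4 had a mean of 28.3 in control and 7.25 in knockout islets, and those without it 0.893 and 31.3.

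Summed over all transcripts, Dpy30 read 29.2 ± 3.22 CPM in control and 38.6 ± 12.7 CPM in knockout islets, a log2 fold change of 0.40 (SE 0.23) that did not pass the threshold (adjusted p = 0.298, edgeR quasi-likelihood test). The knockout libraries read 31.9, 53.2 and 30.7 CPM, and without knockout replicate 2 the log2 fold change was 0.10 (adjusted p = 0.685). With an offset for average transcript length the log2 fold change was 0.99 and passed it (adjusted p = 0.0296). The authors' deposited table lists Dpy30 at a log2 fold change of 0.88 with an adjusted p of 0.000957.

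Knockout islets differed from control islets in 1634 of 16430 tested genes, 674 higher and 960 lower in knockout islets (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Of these, 1074 differed by a fold of 2 or more, 414 higher and 660 lower. The largest rises among genes of at least 5 CPM were those of Xpnpep2, a membrane aminopeptidase (log2 fold change 7.64, SE 0.57), the sugar phosphate transporter Slc37a2 (5.57, SE 0.31), the apolipoprotein Apoa1 (5.52, SE 0.44) and the neurokinin receptor Tacr3 (4.93, SE 0.26). They were followed by S100a4 (3.34), the homeobox gene Barx2 (3.29), Srl (3.25) and the tight junction gene Cldn2 (2.93). The largest falls were those of the alcohol dehydrogenase Adh1 (-4.60, SE 0.37), the endothelin Edn3 (-4.45, SE 0.37), the mucin Muc4 (-4.44, SE 0.51) and Mlph (-4.32, SE 0.50). The glucagon receptor gene Gcgr (-4.11), the tight junction gene Cldn7 (-3.93), Hapln4 (-3.79) and the imprinted gene Nnat (-3.45) followed. Adjusted p-values of these 16 genes ran from 0.000447 for Slc37a2, Tacr3 and Cldn7 to 0.0235 for Hapln4, whose call was kept in 3 of the 6 fits that each left out 1 library. With the replicate number as a block the calls were 1138 higher and 1292 lower. With the acinar level as a covariate, added after the data were seen, there were 312 calls, and of 78 called genes followed through the settings 49 lost their call. Of the 16 genes above, Gcgr (log2 fold change -3.78, adjusted p = 0.0545) and Hapln4 (-4.844, adjusted p = 0.0729) lost it. Among the other genes followed, the calls of Slc2a2, Ffar1, Slc30a8, Ucn3, Kcnj11, Isl1, Rbp4, Gc, Ndufb6, Me3, Sdhb, Eno2, Tspan8, Dcx and Crmp1 were kept and those of the rest were lost. There were 970, 797 and 784 calls without control replicates 1, 2 and 3, and 986, 1330 and 737 without knockout replicates 1, 2 and 3. All 6 such fits shared 547 of the 1634 calls (174 higher, 373 lower), and of 70 called genes among those chosen by the naming rule 38 were called in all 6.

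Genes for islet hormones were lower in knockout islets as a group (8 measured, 3 lower and 0 higher over all genes tested, 6 lower adjusted over the list alone). Pancreatic polypeptide (Ppy) fell from 3586 ± 1051 to 691 ± 291 CPM (log2 fold change -2.38, SE 0.35, adjusted p = 0.00694), peptide YY (Pyy) by 1.44 on the log2 scale (adjusted p = 0.0103) and somatostatin (Sst) by 0.91 (adjusted p = 0.0217, called in 2 of the 6 fits that left out a library). With the acinar level as a covariate Ppy (-1.997), Pyy (-1.344) and Sst (-1.126) lost their calls (adjusted p = 0.0746, 0.103 and 0.0662). Ins1 had a mean of 56301 ± 20160 CPM in control and 25170 ± 6973 CPM in knockout islets, and Ins2 125570 ± 29900 and 57628 ± 15950 CPM. Their log2 fold changes of -1.16 and -1.12 missed the threshold (adjusted p = 0.0779 and 0.069) and passed it with the replicate block (adjusted p = 0.0219 and 0.0229). With the block 5 of the 8 hormone genes were called lower, and DESeq2 called Ins1, Ins2 and Gcg as well (adjusted p = 0.000902, 0.000136 and 0.000223). Glucagon (Gcg, -1.01, adjusted p = 0.0629), amylin (Iapp, -0.51) and ghrelin (Ghrl, -0.37) were not called. Camera placed the list below other genes (adjusted p = 7.75e-05; adjusted p = 0.17 with an estimated correlation). Ins1 and Ins2 are close paralogs, so the division of reads between them is an estimate.

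Genes of beta cell maturity and function fell, while regulators of islet and beta cell identity were mixed. Isl1 (log2 fold change -1.17), Mlxipl (-0.87), Pax6 (-0.80), Rfx6 (-0.66) and Nkx2-2 (-0.59) were called lower, and others did not pass the test. Of 24 measured genes of maturity and identity, 9 were lower and 0 higher (11 lower and 2 higher adjusted over the list alone). Slc2a2, the glucose transporter of mouse beta cells, fell from 868 ± 213 to 87.3 ± 11.6 CPM (log2 fold change -3.31, SE 0.24, adjusted p = 0.000741). The fatty acid receptor gene Ffar1 fell by 2.78 on the log2 scale, the granule zinc transporter gene Slc30a8 by 1.73 and urocortin 3 (Ucn3), a marker of mature beta cells, by 1.60. The log2 fold changes of Mafa (0.59, adjusted p = 0.097; 0.0286 with DESeq2), Pdx1 (-0.31, adjusted p = 0.333), Nkx6-1 (-0.50, adjusted p = 0.186) and G6pc2 (-0.51, adjusted p = 0.345) did not pass the threshold. The list stood below other genes (camera adjusted p = 9.4e-06; adjusted p = 0.398 with an estimated correlation).

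**Figure D2:**
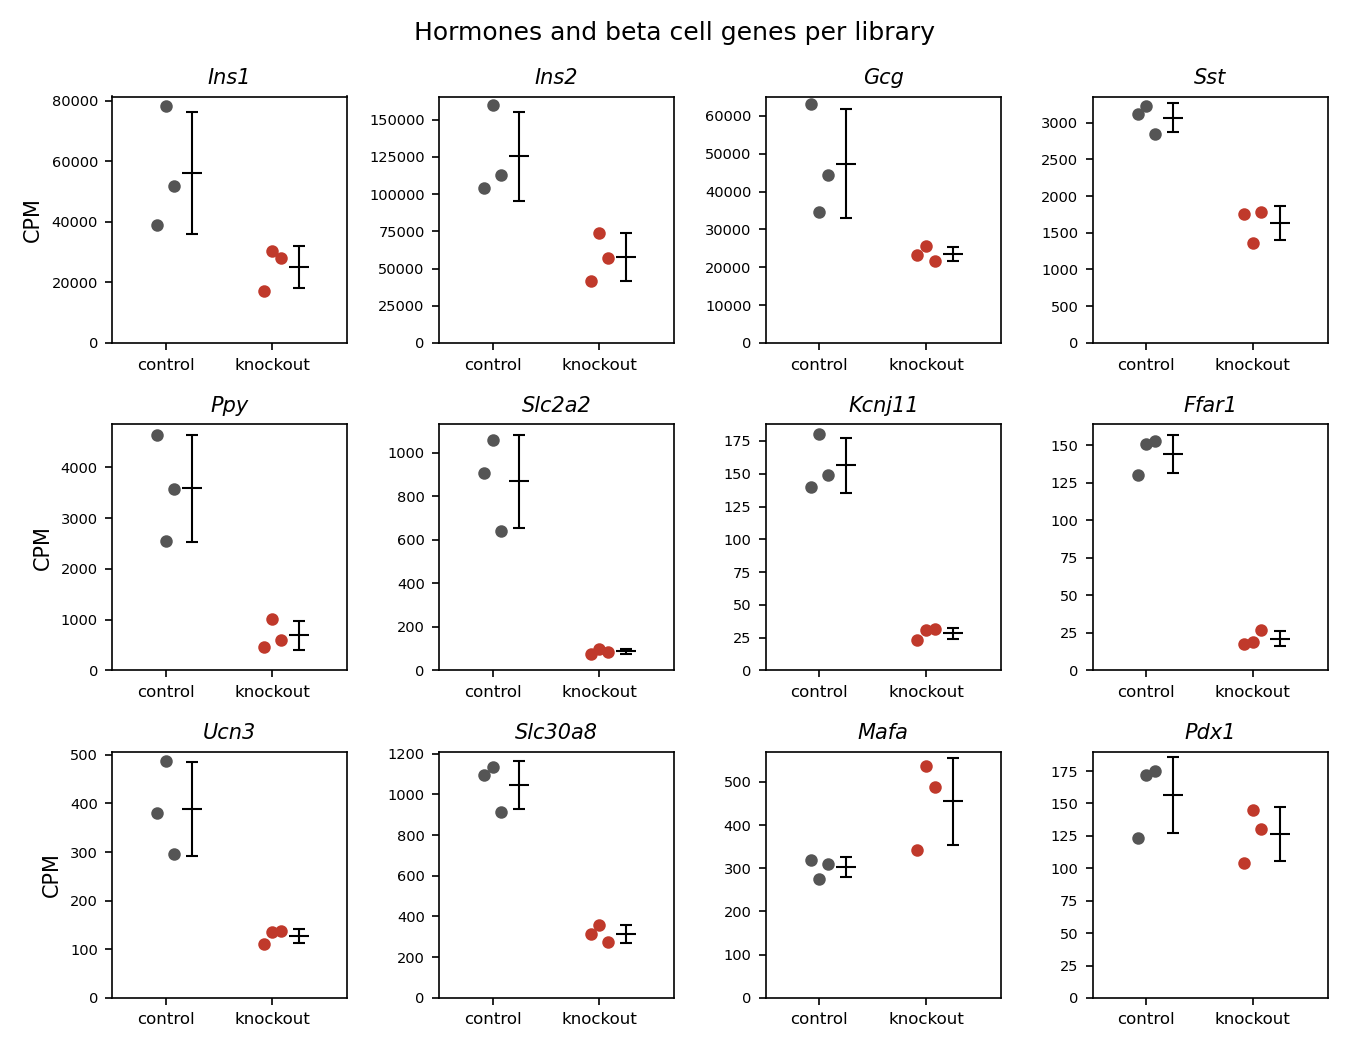
Scaled read counts (CPM) of hormone and beta cell genes in the 3 control and 3 knockout libraries. Points are libraries, and the horizontal mark with its bar is the mean with SD. Slc2a2 had a mean of 868 in control and 87.3 in knockout islets, while Mafa had 302 and 454.8.

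Stimulus-secretion coupling, the steps from glucose entry to calcium-triggered exocytosis, held 11 lower and 0 higher genes of 29 (16 lower adjusted over the list alone). Besides Slc2a2, Ffar1 and Gcgr these included Kcnj11, the pore of the ATP-sensitive potassium channel, which fell from 156.4 ± 21.1 to 28.4 ± 4.24 CPM (log2 fold change -2.46, SE 0.17, adjusted p = 0.000741). The list stood below other genes (camera adjusted p = 9.72e-10; adjusted p = 0.17 with an estimated correlation). Genes of secretory granules and exocytosis did not move as a list (4 lower, 1 higher of 30, camera adjusted p = 0.251). Slc30a8 fell by 1.73, Rab27a by 0.84, Sytl4 by 0.70 and Rph3al by 0.56 on the log2 scale. The calls of Rab27a, Sytl4 and Rph3al were kept in 2, 1 and 1 of the 6 fits that left out a library. The list held 1 lower and 0 higher genes without any 1 control library or without knockout replicate 3. Without knockout replicate 1 it held 2 lower genes, and without knockout replicate 2 it held 5 lower and 3 higher.

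Among 26 islet transcription factors, 10 were lower and 0 higher (14 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.37e-06; adjusted p = 0.17 with an estimated correlation). Isl1 fell by 1.17 (SE 0.13), St18 by 1.36 (SE 0.17) and Myt1 by 1.32 (SE 0.23) on the log2 scale. With the acinar covariate St18 (-1.325) and Myt1 (-1.14) lost their calls (adjusted p = 0.0535 and 0.123). The number called lower was 4, 5 and 3 without control replicates 1, 2 and 3, and 4, 7 and 3 without knockout replicates 1, 2 and 3. In each of these fits except the one without knockout replicate 2, 1 factor was called higher. Without any 1 control library or without knockout replicate 3, 27 factors were measured.

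Alpha and delta cell genes were also lower. Of 10 alpha cell genes 4 were lower and 1 higher (camera adjusted p = 0.0323; adjusted p = 0.503 with an estimated correlation). Slc38a5 fell by 1.69 and Slc7a2 by 1.10 on the log2 scale, whereas Gc, the vitamin D binding protein, rose from 117.03 ± 11.7 to 436.9 ± 31.5 CPM (log2 fold change 1.90, SE 0.15). The camera call of this list was lost without control replicate 3 (adjusted p = 0.0871), knockout replicate 1 (0.0511) or knockout replicate 2 (0.0609), and 2 members were called lower without control replicate 3. Of 6 delta cell genes 2 were lower, Sst and Rbp4, the latter by 1.63 on the log2 scale (camera adjusted p = 0.00353; adjusted p = 0.392 with an estimated correlation), and 4 were lower with the replicate block. Rbp4 was called in all 6 fits that left out a library, and without any 1 control library or without knockout replicate 3 it was the 1 delta cell gene called.

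Genes that are normally silent in beta cells stood above other genes as a list, with few single calls: 2 of 25 were higher and 0 lower (camera adjusted p = 9.61e-05; adjusted p = 0.503 with an estimated correlation), and 7 were higher with the replicate block. Without control replicate 3 or knockout replicate 3, 1 was higher. Arhgdib rose by a log2 fold change of 1.48 and Pdgfra by 2.22, from 1.17 ± 0.26 to 5.46 ± 1.76 CPM. Pdgfra is also a mesenchymal gene and stands in that list too. The medians per library, as log2 CPM minus the mean over 6 libraries, were -0.02, -0.62 and -0.15 in control and 0.27, -0.06 and 0.61 in knockout islets for the silent genes. Those of mesenchymal genes were -0.20, -1.02, -0.06, 0.40, -0.13 and 0.93. Both lists were lowest in control replicate 2 and highest in knockout replicate 3, while control replicates 1 and 3 stood in opposite order. The likeness of the 2 lists was not tested. Lactate dehydrogenase A (Ldha) had a log2 fold change of 0.92 (adjusted p = 0.0821; adjusted p = 0.0159 with the replicate block), and the repressor gene Rest 0.57 (adjusted p = 0.328). In the list of immature endocrine and progenitor genes, Npy (called in 2 of the 6 fits that left out a library) rose by 1.74 and gastrin (Gast) by 2.37, and Fev fell by 1.60 on the log2 scale, without a shift of the list (camera adjusted p = 0.505). Neurog3 (-0.22) and Aldh1a3 (1.21) were not called.

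Nuclear genes for subunits of oxidative phosphorylation (OXPHOS) complexes were higher in knockout islets: 25 of 75 rose and 0 fell (60 rose adjusted over the list alone), with a median log2 fold change of 0.57. Atp5b rose from 513.5 ± 43.8 to 902.1 ± 67.0 CPM (log2 fold change 0.81, SE 0.16, adjusted p = 0.0169), Ndufb6 by a log2 fold change of 1.07, Cox5a by 0.74 and Atp5d by 0.74. The list stood above other genes (camera adjusted p = 2.35e-18; adjusted p = 0.452 with an estimated correlation). The number of called members was 0 without control replicate 1, 1 without control replicate 2 or control replicate 3, 11 without knockout replicate 1, 14 without knockout replicate 2 and 10 without knockout replicate 3. OXPHOS transcripts were short, with a median of 499.3 bases of effective length against 2223 over all tested genes, and log2 fold changes fell with length across genes (Spearman -0.311 over genes above 8 CPM, which are not independent replicates; -0.155 without knockout replicate 2). In knockout replicate 2 alone, levels relative to the mean of 6 libraries fell with length (Spearman -0.512, against 0.021 to 0.29 in the others), and it had the highest OXPHOS median (0.54).

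Of 19 genes in the tricarboxylic acid cycle list, 4 rose: Me3 (log2 fold change 2.10, SE 0.22), Idh3a (0.75), Sdhb (0.74) and Idh3b (0.67) (camera adjusted p = 0.00249; adjusted p = 0.17 with an estimated correlation). Me3, with the largest rise, encodes a malic enzyme, which is not a step of the cycle itself. Sdhb is also a member of the OXPHOS list. Without control replicate 1 or 2, 1 gene of the list was called, and without control replicate 3 or knockout replicate 1, 2 were. Of 16 glycolysis genes, Pfkp (0.93) and Pkm (0.63) rose and Eno2 (-0.79) fell (camera adjusted p = 0.0142; adjusted p = 0.268 with an estimated correlation). With the replicate block Pkm and Eno2 lost their calls (adjusted p = 0.0582 and 0.0543), and each was called in 1 of the 6 fits that left out a library. Of 77 cytosolic ribosomal protein genes edgeR called 0, also when adjusted over the list alone (15 had an unadjusted p below 0.05, and DESeq2 called 2 and limma-voom 1), while the list stood slightly above other genes (median log2 fold change 0.22, camera adjusted p = 4.3e-05; adjusted p = 0.667 with an estimated correlation). The median was 0.14 without knockout replicate 2. These transcripts are short, with a median effective length of 468, and the 2639 genes above 8 CPM with the shortest transcripts, up to a length of 1471, had a median log2 fold change of 0.22 too. Of 13 mitochondrially encoded mRNAs edgeR, DESeq2 and limma-voom called 0, and 0 had an unadjusted p below 0.05 (camera adjusted p = 0.546).

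**Figure D3:**
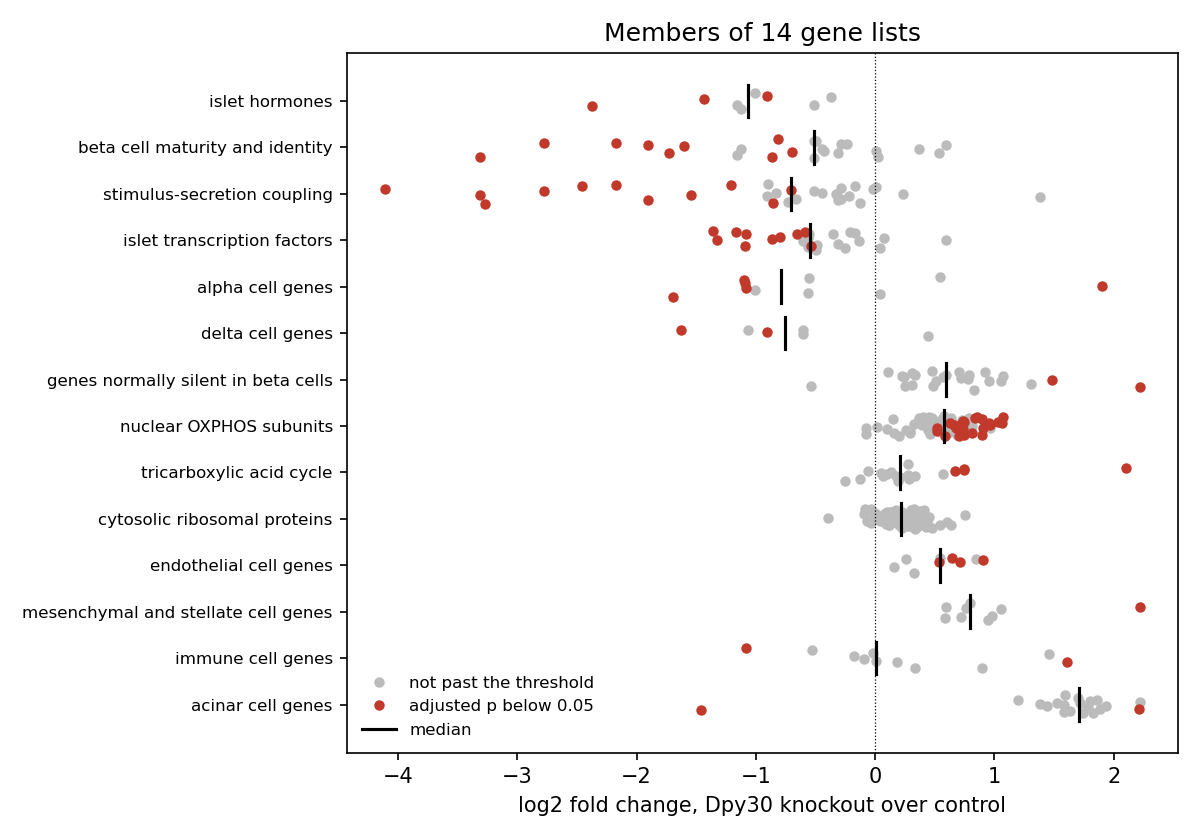
Log2 fold changes, knockout over control, of the members of 14 gene lists. Each point is a gene, red where its adjusted p is below 0.05, and the vertical mark is the list median, which was -1.07 for islet hormones, 0.57 for nuclear OXPHOS subunits and 1.71 for acinar cell genes.

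Cholesterol synthesis genes were lower as a list, with 2 of 18 members lower and 0 higher (5 lower adjusted over the list alone) and 5 lower with the replicate block (camera adjusted p = 0.0132; adjusted p = 0.638 with an estimated correlation). This camera call was lost without control replicate 3 (adjusted p = 0.167, 1 called member) or knockout replicate 2 (0.0683). Genes of the unfolded protein and integrated stress response stood below other genes (camera adjusted p = 0.0119; adjusted p = 0.392 with an estimated correlation) with 0 of 18 called by edgeR, 2 by DESeq2 and 1 by limma-voom, 3 at an unadjusted p below 0.05 and 3 lower with the replicate block. Dnajc3 had a log2 fold change of -0.77 (adjusted p = 0.0506; adjusted p = 0.0302 with the replicate block).

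Markers of non-endocrine cells differed between libraries. Acinar genes took 0.307, 0.463 and 0.137% of scaled reads in control and 0.680, 0.333 and 1.97% in knockout islets, and their list stood above other genes (median log2 fold change 1.71, camera adjusted p = 0.000144; adjusted p = 0.638 with an estimated correlation), with Try5 higher (2.21) and Bhlha15 lower (-1.46). Without knockout replicate 3 the median was 0.74, and without knockout replicate 2 edgeR called 4 acinar genes higher. Trypsinogen genes are near-identical copies, so the value of Try5 is uncertain, and its call was lost with the replicate block (adjusted p = 0.0587). Try5 and Bhlha15 were each called in 2 of the 6 fits that left out a library. Of 9 endothelial genes 4 rose: Pecam1 (0.90), Esam (0.71), Plvap (0.65) and Emcn (0.54) (camera adjusted p = 0.000395; adjusted p = 0.452 with an estimated correlation). Of the 6 fits that left out a library, Pecam1 was called in 0, Esam in 3, and Plvap and Emcn in 1 each. All 4 lost their calls with the acinar covariate (adjusted p = 0.0714 for Esam to 0.271 for Plvap). Their log2 fold changes were then 0.98 for Pecam1, 0.87 for Esam, 0.53 for Plvap and 0.59 for Emcn. Without control replicate 2, control replicate 3 or knockout replicate 1 edgeR called 0 endothelial genes, and without control replicate 1 or knockout replicate 3 it called 1; with all 6 libraries, 6 had an unadjusted p below 0.05 and DESeq2 called 5. Of 9 mesenchymal and stellate genes Pdgfra was called, and all 9 with the replicate block (camera adjusted p = 0.000483; adjusted p = 0.503 with an estimated correlation). Immune cell genes went both ways, with Cd68 higher (1.61) and C1qa lower (-1.08, called in 2 of the 6 fits that left out a library), and did not move as a list (camera adjusted p = 0.447).

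The remaining lists did not pass camera. Of 20 subunits of H3K4 methyltransferase complexes, Bod1 (0.90) and Cxxc1 (0.62) rose (camera adjusted p = 0.583), Cxxc1 in 0 of the 6 fits that left out a library. Of 5 H3K4 demethylases edgeR called 0 and DESeq2 1, 3 had an unadjusted p below 0.05, and 1 was lower with the replicate block (camera adjusted p = 0.248). Ductal genes (camera adjusted p = 0.594) held 2 lower genes and 1 higher gene of 7, among them Tspan8 (-1.94), which fell, and Spp1 (0.72), which rose; their median was positive while camera gave a lower direction. Spp1 was called in 2 of the 6 fits that left out a library. Cell cycle genes (0.379; 3.14e-05 and 4 lower genes without control replicate 1) held 1 lower gene, Ccnd1 (-1.13), and Mki67 (-0.79, adjusted p = 0.178) was not called. Of p53 targets (0.281; 0.0445 without control replicate 1) Phlda3 rose (1.29) and Cdkn1a (1.47) was not called (adjusted p = 0.111; adjusted p = 0.00759 with the replicate block). The edgeR call of Phlda3 was lost without control replicate 2 (adjusted p = 0.0561) or control replicate 3 (0.0529), which left 0 called p53 targets. In the interferon and antigen presentation list (0.303) B2m rose (0.78) and H2-K1 fell (-0.62, called in 1 of the 6 fits that left out a library). Among Schwann cell (0.505), red blood cell (0.601), Hox (0.0666) and immediate early genes (0.478) edgeR, DESeq2 and limma-voom called 0, and 2, 0, 2 and 0 had an unadjusted p below 0.05. Values in parentheses after a list's name are camera adjusted p-values. Hox genes passed camera as higher without control replicate 1, 2 or 3 (adjusted p = 0.0295, 0.0207 and 0.0317) or knockout replicate 1 (0.00665). In those fits 10 Hox genes were measured, against 8 with all libraries and without knockout replicate 2 or 3. With the replicate block 1 of 8 was called. Immediate early genes differed most within the control group, where Fosb read 3210, 0.47 and 397.3 CPM in replicates 1 to 3, and their median (-0.57) and camera direction (higher) had opposite signs. They passed camera as higher without control replicate 1 (adjusted p = 0.00596) and as lower without control replicate 2 (0.00228).

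The fold changes were set beside the authors' deposited table, which comes from the same libraries and therefore compares methods. That table lists 21341 genes, of which 2471 have an adjusted p below 0.05, 1141 higher and 1330 lower. Across 16425 genes present in both, log2 fold changes correlated at a Pearson r of 0.916 and a Spearman rho of 0.948. With the transcript length offset these were 0.930 and 0.971. Genes are not independent replicates. Whether the authors' fold changes were shrunken is not stated in the sources used here, so the correlations may set shrunken against unshrunken values. Some were smaller in size there, such as Hoxa2 (0.18 there, 1.53 here) and Nr4a1 (-0.07 there, -1.08 here), and Dpy30 was larger (0.88 there, 0.40 here). Of the calls made here, 636 higher and 899 lower genes were called in the same direction in the authors' deposited table and 0 in the opposite direction.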

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

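Of the tests in this part, those on transcript length and on acinar RNA for the OXPHOS genes were set before their results were seen; the label, length correction, hormone share, cell share, dilution and split tests were chosen after. Single outlying libraries were not tested for in these groups of 3. One signal lay in transcript-level data that the gene-level comparison does not use: transcripts without exon 4 took 81.2% of Dpy30 reads in knockout islets, against 3.15% in control islets.

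The first pattern was that the Dpy30 total was not lower in knockout islets. A swap of control with knockout libraries that mixes the groups is argued against, since another split of the libraries would then give the most calls, and the highest of the others gave 47 by DESeq2 against 2633. A single wrong label would give a library the other group's share of Dpy30 reads without exon 4, and exchanged labels would put the loss of exon 4 in control islets; the share was at least 80.5% in every knockout and at most 5.24% in every control library, which argues against both, though exon 4 was singled out with these values in view. A length correction raised the log2 fold change by 0.589, so the higher value in the authors' deposited table may come from a correction for the shorter transcript. That a transcript joining the exons around exon 4 keeps the gene total up remains a hypothesis, and whether the remaining reads with exon 4 come from cells without deletion was not tested.

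The second pattern was the rise of nuclear OXPHOS genes. The median of the list, 0.57, lay at percentile 100 of 10000 random lists matched on length, level and GC content, whose medians had a mean of 0.24, and it was 0.40 after the length trend was removed (0.396 with the replicate block as well) and 0.435 without knockout replicate 2, again at percentile 100. It was 0.816 with the acinar level as a covariate and 0.5747 with library sizes without hormones. Without scaling factors the lower share of hormone reads would raise every other gene's share by a log2 value of 0.208 (SE 0.0371 between libraries). The list median is on TMM-scaled values, where the median log2 fold change of all tested genes was 0.006, so the 0.208 is not a part of it. These values argue against length, acinar RNA or the loss of hormone reads as the whole cause, though length may account for part. Members of the list vary together between libraries, so the percentile describes these libraries and is no test across mice; with an estimated correlation the list's adjusted p was 0.452, and an effect of the knockout on these genes remains a hypothesis.

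The third pattern was the fall of beta cell function genes. A lower share of beta cells as the whole cause would lower alike those members expressed in beta cells alone. The SD of log2 fold changes between the 24 members was 0.996 against a median SE of 0.23, from -3.31 for Slc2a2 to 0.59 for Mafa. Dilution by RNA of non-endocrine cells would lower alike those alpha, beta and delta genes that such cells lack. The SD over the 40 members of those lists was 0.961 against a median SE of 0.22. Members also expressed in other cells would fall less under either cause, and expression by cell type was not measured. These spreads alone therefore do not decide. List medians of delta cell and endothelial genes moved apart by 1.33 (SE 0.06 between libraries), which a lower share of beta cells alone would not give. Neither list shares a member with the beta cell list, so this gap does not decide why beta cell genes fell. In the delta and endothelial lists 2 of 6 and 4 of 9 members were called, 0 endothelial genes in 3 of the fits that left out a library. Both lists missed camera with an estimated correlation (adjusted p = 0.392 and 0.452). A gap between endothelial and immune lists, tried for dilution after a test on an assumed cell profile had been dropped as unsound, did not decide (0.40, SE 0.32). A shift in cell shares may still contribute to the fall.

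The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 1634 called genes, and 1 of the 10 splits, the real one, gave as many. The highest of the other splits gave 0 by edgeR, 47 by DESeq2 and 1027 at an unadjusted p below 0.05, against 2633 and 4512 for the real split. The real split parts all 3 pairs of same-numbered libraries (2430 calls with the replicate block); the 3 other splits that do so gave at most 15 calls by DESeq2 and 293 genes at an unadjusted p below 0.05, and the highest values came from splits that keep 2 pairs together.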

How the results depend on the processing

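The acinar covariate and the correlations with 1 library left out were chosen after the data were seen; the other settings were planned. No gene called in the main comparison was called in the opposite direction in any setting. RLE, upper quartile and hormone-free scaling, limma-voom, both filters, the length offset and protein-coding genes alone kept the counts of called genes within 1.5 times. Calls rose from 1634 to 2633 with DESeq2 (1198 higher). The replicate block gave 1138 higher genes. Pax6, Nkx2-2, Rfx6 and Mlxipl were not followed through the settings. For the other genes and the lists named here, the block changed no other call than those printed beside their results. Calls fell to 312 with the acinar covariate (93 higher, 219 lower), which leaves 1 degree of freedom fewer (of 78 called genes followed through the settings 49 lost their call, 0 with a changed sign), to 466 at an adjusted p below 0.01 (140 higher, 326 lower), and to 1074 at an absolute log2 fold change of at least 1 (414 higher). Leaving out 1 library gave 737 (without knockout replicate 3) to 1330 calls (without knockout replicate 2), 243 to 550 higher and 464 to 780 lower; without control replicates 1, 2 and 3 there were 970, 797 and 784 calls and without knockout replicate 1 there were 986, with fewer libraries in each fit. The Dpy30 log2 fold change passed the threshold at 0.9868 with the length offset and was 0.0974 (without knockout replicate 2) to 0.5435 with 1 library left out. Of 16 lists past camera, 0 passed with an estimated correlation and 7 passed fry, and leaving out 1 library gave 14 to 20. The correlation with the authors' deposited table was 0.935 for genes of at least 1 CPM and 0.8211 to 0.8598 with 1 library left out. Signs changed for genes that were never called: Ghrl (-0.6983 to 0.1276 with 1 library left out, the highest without control replicate 3, and 0.2389 with the acinar covariate) and Neurog3 (-0.4955 to 0.02899, the highest without knockout replicate 1). Immediate early genes had medians of -1.103 (without control replicate 2, camera direction lower) to 0.4517 (without control replicate 1), and the median changed from -0.5668 to 0.2112 with the replicate block. Except where fewer libraries or a stricter threshold explain it, the cause was not tested. At this depth and with 3 mice per group edgeR found 24.8% of simulated 2-fold changes and DESeq2 50.4%, with more false calls. The simulated sets held 200 changed genes, so their adjusted threshold was stricter than that of the data. The calls in the data include changes under 2-fold, and the share of such changes that was missed was not measured.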

Other observations

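Both tests in this part were chosen after the result was seen, with lists written from general knowledge once some of their members had been noticed among the called genes, so the lists are not independent evidence.

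Imprinted genes, which are expressed from 1 parental copy, were called more often than other genes of similar level: 13 of 39 measured (2 higher, 11 lower), against a mean of 3.73 in 10000 random lists matched on level, which put the count at percentile 100. The replicate block gave 2 higher and 16 lower. Nnat fell from 122.4 to 11.2 CPM (log2 fold change -3.45, SE 0.36), Zim1 by 2.57, Usp29 by 1.32, Igf2 by 1.53, Dlk1 by 1.07 and Peg3 by 0.85 on the log2 scale. With 1 library left out Igf2 and Dlk1 were each called in 1 of 6 fits and Peg3 in 2, and with the length offset Igf2 and Dlk1 were not called (adjusted p = 0.0929 and 0.0645). H19, which neighbours Igf2, was higher (3.57, SE 0.62) at a low level, 0.166 CPM in control and 2.04 CPM in knockout islets. The random lists were drawn gene by gene, so the percentile takes no account of imprinted genes that vary together and is no test across mice. With camera the list had p = 0.000275, and p = 0.0728 with an estimated correlation. That Dpy30 loss alters imprinted genes in islets is a hypothesis; a change of cell shares was not tested for this list.

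Some neuronal genes were higher: Crmp1 rose by a log2 fold change of 1.95 (SE 0.19), Dcx by 1.55 (SE 0.17), Tubb3 by 1.18 (SE 0.26) and Mapt by 0.97 (SE 0.20), Tubb3 and Mapt being called in 2 and 3 of the 6 fits that left out a library. Of 37 neuronal genes 5 rose and 3 fell (10 and 5 with the replicate block), and the median of the list, 0.28, lay at percentile 99.94 of level-matched random lists. Camera did not call the list (p = 0.0563; p = 0.583 with an estimated correlation), and 3 members, Kif1a, Elavl4 and Camk2b, fell, so a rise of the whole group is not shown.

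Knockout replicate 2 differed from the rest in read composition. Lars2 read 28297 CPM there and 213 to 475 CPM in the other libraries, and its levels relative to the mean of the 6 libraries fell with transcript length (Spearman -0.512 across genes). The correlation of fold changes with length over genes above 8 CPM was -0.311 with this library and -0.155 without it. The OXPHOS median was 0.43 without this library.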
